A study of Mus musculus with 11 samples.

How the data were processed

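RNA was measured by bulk RNA sequencing in Tregs sorted as live CD3+ CD4+ Foxp3+ cells from visceral adipose tissue and spleen. Per the labels' protocols, RNA was isolated with a Quick-RNA MicroPrep kit, cDNA was made with the SMART-seq kit for low input and libraries were made with Nextera XT, a kit that does not mark the strand. Per the submitters' processing notes, STAR and mm10 were used for alignment. The read counter, the gene models, the filter that left 10992 genes and the denominator of the scaling are not given in the sources used here. The authors deposited 1 table with an RPKM value (reads scaled by gene length and library size) for each gene and sample, per the file headers. RPKM values are not counts, and low values did not give the worth of 1 read, so the read depth of each library is unknown and no counting error is given. Over the columns used, 128 values are listed at 0.

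Groups and replicate numbers came from the labels, which name 11 samples. Of these, 10 have a column whose name matches their label: 3 VAT WT, 3 VAT KO, 2 spleen WT and 2 spleen KO. Spleen KO replicate 1 has no matching column and was not analysed here. The table also holds 1 column of per-sample values that matches no sample in the labels. It was not used in any step. The design had assumed all 11 samples. With 10, spleen has 2 against 2 samples, so that its exact permutation test has 6 splits and a smallest p of 0.333. The table's Entrez identifiers were found in a reference table of GRCm38.p6, which is mm10, for 10987 genes, and 15 symbols that had become dates were restored by these identifiers. Coordinates are from that table and count from 1. Transcript lengths were taken from GENCODE and covered 98.8% of tested genes.

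Values were analysed as log2(RPKM + 1), a pseudocount of 1, over the 10429 genes with an RPKM of at least 1 in at least 2 samples. One limma model was fitted with the 4 group means and no covariate (trend on, robust off), with 6 residual and 6.44 prior degrees of freedom, so that all groups shared the estimate of each gene's spread. Tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Comparisons were KO against WT in VAT and in spleen, VAT against spleen in WT and in KO, and the interaction of genotype and tissue. Errors of fold changes are standard errors from limma, and those of RPKM are SDs over the samples of a group. Srebf2 and Foxp3 were also tested with a two-sided exact permutation test within each tissue.

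Gene lists, the main tests, the rule for named genes and the alternatives were fixed before the data were examined. Tests chosen later are said to be so below. The 27 lists held 452 members and covered cholesterol synthesis, sterol uptake and SREBP control, sterol efflux, isoprenoid enzymes, fatty acid synthesis and oxidation, the adipose Treg programme, core Treg genes, naive and lymphoid homing, T cell receptor induction, immediate early and dissociation genes, proliferation, interferon, type 1 and cytotoxic, type 17, oxidative phosphorylation, glycolysis, ER stress, apoptosis, ribosomal proteins and markers of 7 kinds of other cells. The 23 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list moves on its own, were run beside it. The rule named Srebf2 and Foxp3, the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 RPKM in the higher group and groups that did not overlap, or the 4 genes with the smallest p where none was called, and 2 to 4 members with the smallest p of each list described. Genes named outside the rule are said to be so. Some genes that the rule would name are not reported here, and in 2 lists the next member by p was named in their place. Other splits of the 6 VAT libraries were refitted in all 10 ways.

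Alternatives were pseudocounts of 0.1 and 5, no filter, a filter at a mean of 5 RPKM, quantile normalization, scaling by median ratios, the 2 compared groups alone, sample weights, a robust spread, a 2-fold threshold, replicate numbers as a block, and each library left out in turn. The averaged effect of the deletion over both tissues was added after the data were seen. The fit was tested on 20 simulated tables of 10429 genes with 200 changed genes and noise independent between genes. Changed genes were drawn from those with higher levels, and each gene had 1 spread in all libraries. The real spread was wider in spleen WT than in spleen KO (median SD 0.279 against 0.148 log2 units), so recovery in spleen may be lower than simulated. In VAT it recovered 87.2% of 2-fold and 99.8% of 4-fold changes with 5.4% of calls false, and in spleen 63.1% and 99.4% with 4.8% false. The 200 planted changes ease the Benjamini-Hochberg threshold, while the real data gave 44 calls in VAT and 0 in spleen. Recovery in the real data may thus be lower, above all in spleen. There Srebf2 (log2 change -2.45) and Apobec3 (-2.01) did not pass, though both were past 4-fold. Software was R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.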

Results

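The data described regulatory T cells (Tregs), the CD4 T cells that carry the transcription factor Foxp3 and restrain immune responses, from visceral adipose tissue (VAT) and spleen of male mice aged 25 weeks. All mice carried a Foxp3-driven YFP-Cre recombinase, and the Srebf2 gene was either wild type (WT) or flanked by loxP sites on both copies and so open to deletion in Tregs (KO). Srebf2 encodes SREBP2, the transcription factor that drives cholesterol synthesis and uptake. RNA levels as RPKM, reads scaled by gene length and library size, were analysed for 3 VAT WT, 3 VAT KO, 2 spleen WT (replicates 2 and 3) and 2 spleen KO samples (replicates 2 and 3), each covering 10992 genes. Spleen KO replicate 1 was not analysed here. Read depth was unknown. Each library's RPKM summed to between 185319 and 210778, and 9551 to 9774 genes per library reached 1 RPKM. Nothing in the labels said that the libraries of a group came from separate mice, so p-values measured only the spread between these samples, which may be technical. All fold changes are on the log2(RPKM + 1) scale, which understates changes of low genes, and all adjusted p-values of genes are from limma.

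Tissue separated the libraries more than genotype did. The leading principal component held 63.8% of the variance and placed VAT WT between 33.8 and 39.3, VAT KO between 21.1 and 28.4, and the 4 spleen libraries between -54.3 and -42.2, so that every VAT KO library lay nearer to spleen than every VAT WT library. The next component held 11.8% and set spleen WT replicate 2 apart, at -42.8 against 14.1 to 17.1 for the other 3 spleen libraries. The correlation across genes between the 2 spleen WT libraries was 0.932, against 0.968 to 0.974 between replicates of the other groups. The median SD per gene was 0.28 log2 units in spleen WT, 0.15 in spleen KO, 0.19 in VAT KO and 0.19 in VAT WT.

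**Figure D1:**
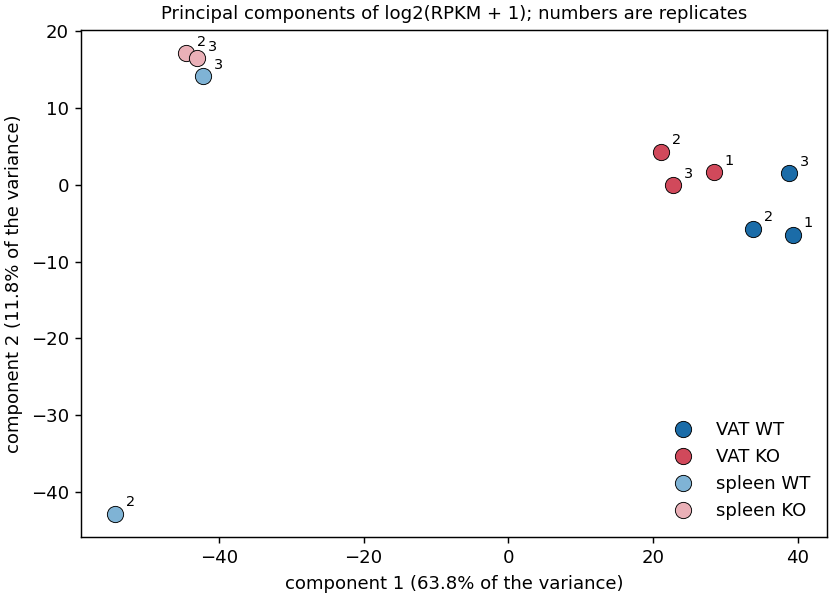
Position of each of the 10 libraries on the first and the second principal component of log2(RPKM + 1), in units of the component scores, with 1 point per library and the group given by the marker. VAT KO libraries lie between 21.1 and 28.4 and VAT WT libraries between 33.8 and 39.3 on the horizontal axis, while spleen WT replicate 2 lies at -42.8 on the vertical axis.

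The targeted gene was checked in every library. Srebf2 (Entrez 20788; chromosome 15, 82147269 to 82205379 in mm10) stood at 0.263, 0.6 and 1.228 RPKM in the 3 VAT KO libraries against 16.599, 15.583 and 30.532 in VAT WT. Its mean in VAT KO was 3.33% of WT, 0.697 ± 0.490 against 20.9 ± 8.35 RPKM (SD, n = 3 each). The log2 change was -3.67 ± 0.33 (SE), a 12.7-fold drop on that scale (limma adjusted p = 0.00081), and the exact permutation test, two-sided, gave p = 0.1, the smallest p that 3 against 3 allow. In spleen, Srebf2 stood at 2.59 and 1.593 RPKM in KO and at 10.506 and 23.195 in WT. The KO mean was 12.4% of WT, 2.09 ± 0.71 against 16.9 ± 8.97 RPKM (SD, n = 2 each), with a log2 change of -2.45 ± 0.40 (limma adjusted p = 0.244; exact permutation p = 0.333, the smallest that 2 against 2 allow). The spleen change was -2.99 without spleen WT replicate 2 and -1.92 without replicate 3, each of which leaves 1 spleen WT sample. The drop in VAT and that in spleen differed by -1.22 ± 0.52 (interaction, adjusted p = 0.692), so a difference between tissues was not shown. A value per gene counts exons outside the floxed part too, so it bounds the share of intact Srebf2 only loosely. Foxp3, which defined the sort, did not pass the threshold between genotypes in either tissue. It stood at 15.2 ± 1.68 RPKM in VAT KO and 15.3 ± 0.53 in VAT WT (n = 3 each; log2 change -0.01 ± 0.16, adjusted p = 0.9995; exact permutation p = 1). In spleen it stood at 8.34 ± 0.74 in KO and 7.83 ± 1.22 in WT (n = 2 each; log2 change 0.09 ± 0.19, adjusted p = 0.888; exact permutation p = 0.667).

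**Figure D2:**
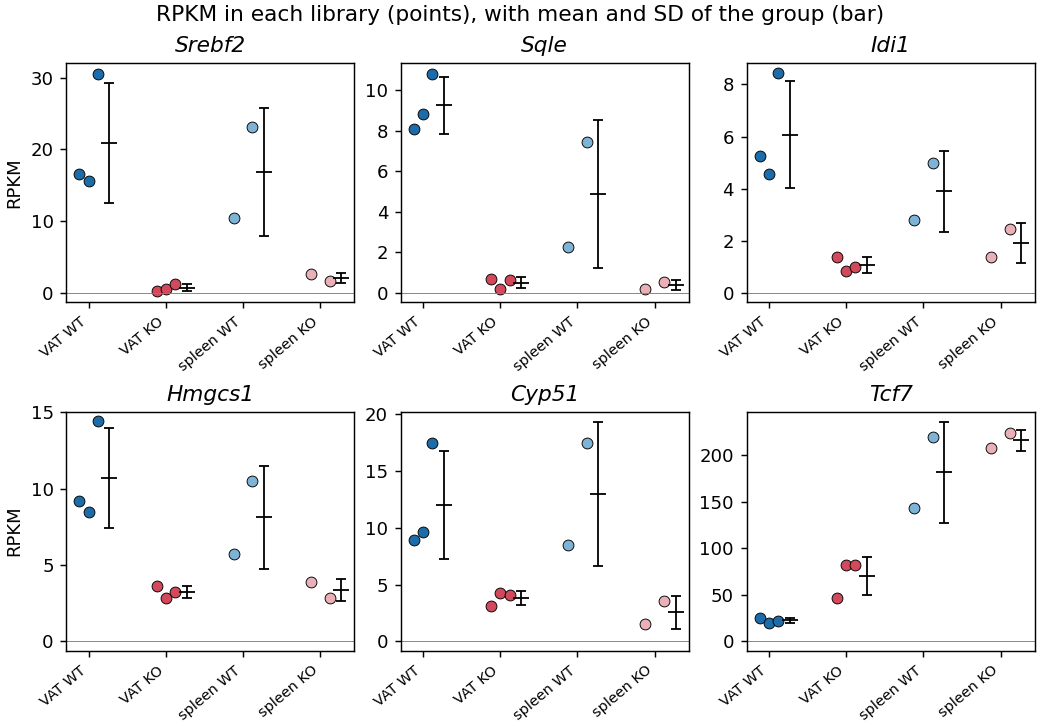
RPKM (vertical axes, linear) of Srebf2, 4 enzymes of cholesterol synthesis and Tcf7 in each of the 10 libraries by group, with 1 point per library and a bar at the mean ± SD of the group (n = 3 in VAT, n = 2 in spleen). Srebf2 lies at 0.263 to 1.228 RPKM in VAT KO and at 15.583 to 30.532 RPKM in VAT WT.

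The comparison of VAT KO with VAT WT asked what loss of Srebf2 changed in adipose Tregs. Genes of cholesterol synthesis fell, and 2 genes of naive T cells, Tcf7 and Txk, rose. Sqle, which makes squalene epoxide, dropped from 9.24 ± 1.39 to 0.509 ± 0.278 RPKM (log2 change -2.77 ± 0.31, adjusted p = 0.00501; SD, n = 3 each). Tcf7, the transcription factor of naive and memory-like T cells, rose from 22.6 ± 2.91 to 70.5 ± 20.7 RPKM (1.56 ± 0.22, adjusted p = 0.0110), and Lrrc32, the surface protein GARP that docks latent TGF-beta on Tregs, rose from 6.91 ± 1.54 to 22.6 ± 6.61 RPKM (1.56 ± 0.23, adjusted p = 0.0143). Limma called 44 genes, 32 higher and 12 lower in KO, 38 of them at least 2-fold. Further falls were in Idi1 (-1.74) and Hmgcs1 (-1.44), enzymes of cholesterol synthesis, in Apobec3 (-1.89), a cytidine deaminase that restricts retroviruses, and in Cbx7 (-1.64), a Polycomb protein. The annotated spans of Apobec3 and Cbx7 overlap, so their values may share reads. The largest rise was in Rflnb (1.95 ± 0.31, adjusted p = 0.0183). The others were Serpina3g (1.70), a serine protease inhibitor whose family of close copies makes its value uncertain, Trat1 (1.55) and Txk (1.42), which act in T cell receptor signalling, Cd9 (1.52), a tetraspanin, and Cd96 (1.36), a receptor of T and NK cells. The count rested on single libraries: it was 2 without VAT KO replicate 3 or without VAT WT replicate 1 (Srebf2 and Sqle each time), 5 without VAT KO replicate 2, 27 without VAT WT replicate 3, and 19 without spleen KO replicate 2 or without spleen KO replicate 3. Hmgcs1, Cbx7, Cd9, Cd96 and Trat1 did not pass with either of these spleen libraries left out. Without VAT KO replicate 2 neither these nor Tcf7, Txk, Lrrc32, Rflnb, Serpina3g, Apobec3 and Idi1 passed. Txk and Rflnb also did not pass without VAT WT replicate 2, nor Idi1 without VAT WT replicate 3. At an unadjusted p under 0.05 there were 767 genes against 521 by chance.

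Of the fixed lists, cholesterol synthesis stood lowest in VAT KO. All 20 measured enzymes were lower, 4 of them fell, among them Sqle, Idi1 and Hmgcs1, and 12 fell adjusted over the list alone. The median log2 change was -0.66 (camera adjusted p = 2.7e-22; adjusted p = 0.0574 with an estimated correlation). In the list of sterol uptake and SREBP control, 1 of 13 fell (3 adjusted over the list alone). The median was -0.11 (camera adjusted p = 0.00348; adjusted p = 0.106 with an estimated correlation). Tmem97, a sterol-binding membrane protein, stood at -1.22 (adjusted p = 0.227) and Insig1, which holds SREBPs in the endoplasmic reticulum, at -0.97 (0.240). Tmem97 passed without spleen WT replicate 2 (-1.22, adjusted p = 0.0107) or replicate 3 (-1.22, 0.0117). With only genes of a mean RPKM of at least 5 this list was not called (camera adjusted p = 0.0642). Of 12 genes of fatty acid synthesis none passed, singly or adjusted over the list alone, among them Mid1ip1 at -0.64 (adjusted p = 0.389) and Acss2 at -0.44 (0.527). The list was lower, at a median of -0.40 (camera adjusted p = 0.000643; adjusted p = 0.188 with an estimated correlation). The median was -0.06 for 8 genes of sterol efflux (1 fell adjusted over the list alone) and -0.02 for 14 isoprenoid and prenylation enzymes, with no call for either list.

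Among lists of Treg state, all 14 genes of the naive and lymphoid homing list were higher in VAT KO. Tcf7 and Txk rose, and 9 of 14 rose adjusted over the list alone. The median was 0.69 (camera adjusted p = 1.1e-13; adjusted p = 0.106 with an estimated correlation). Lef1, a partner of Tcf7, stood at 0.70 ± 0.16 (adjusted p = 0.123). The adipose Treg programme moved the other way by less, with 18 of 21 genes lower, none past the threshold, 3 falling adjusted over the list alone. The median was -0.28 (camera adjusted p = 1.1e-06; adjusted p = 0.102 with an estimated correlation). In it the chemokine Cxcl2 stood at -0.64 (adjusted p = 0.216), the chemokine receptor Ccr1 at -0.70 (0.238) and Pparg, the nuclear receptor that drives this programme, at -0.60 (0.304). In the core Treg list 1 of 19 rose, Lrrc32 (5 adjusted over the list alone). Izumo1r, the folate receptor FR4, stood at 1.19 (adjusted p = 0.0831), and Nt5e, the ectoenzyme CD73, at 1.05 (0.0831). Izumo1r passed without spleen WT replicate 2 (0.0409), spleen WT replicate 3 (0.0406), VAT KO replicate 1 (0.0419) or VAT WT replicate 2 (0.0408), and Nt5e without VAT WT replicate 3 (0.0318). The core Treg median was 0.21 (camera adjusted p = 0.00362; adjusted p = 0.102 with an estimated correlation). Of 10 type 1 and cytotoxic genes none passed (3 rose adjusted over the list alone), with Prf1, perforin, at 1.10 (adjusted p = 0.132) and Il18r1, a chain of the IL-18 receptor, at 0.79 (0.352). The median was 0.56 (camera adjusted p = 0.00054; adjusted p = 0.236 with an estimated correlation). None of the 18 immediate early and dissociation genes, which rise when tissue is digested, passed, also adjusted over the list alone. Jund stood at -0.41 (adjusted p = 0.375) and Zfp36 at -0.38 (0.413), and the list's median was -0.22 (camera adjusted p = 2.4e-05; adjusted p = 0.126 with an estimated correlation). That last call was lost with quantile normalization (adjusted p = 0.0908). Camera made no call for genes induced by the T cell receptor (median 0.07), proliferation (0.02), interferon response (0.02; 1 rose adjusted over the list alone), type 17 (0.20), fatty acid oxidation (-0.06), oxidative phosphorylation (-0.03), glycolysis (0.05), ER stress (-0.03), apoptosis (0.08; 3 rose and 1 fell adjusted over the list alone) or ribosomal proteins (0.12, adjusted p = 0.0760). For the T cell receptor, proliferation and glycolysis lists, medians lay above 0 while camera's direction was down.

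**Figure D3:**
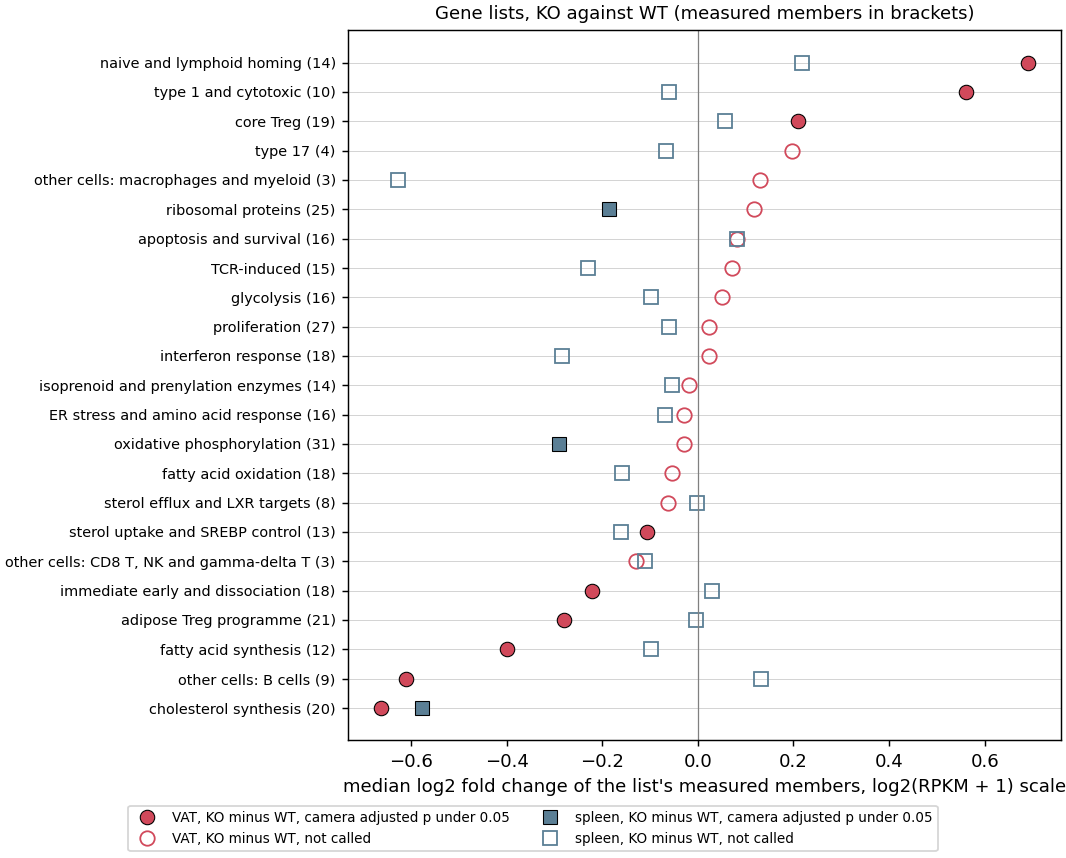
Median log2 fold change, KO against WT, of each tested gene list in VAT and in spleen, with 1 point per list and tissue, filled where camera with the preset correlation called the list at an adjusted p under 0.05. The cholesterol synthesis list lies at -0.66 in VAT and -0.58 in spleen, and the naive and lymphoid homing list at 0.69 in VAT and 0.22 in spleen.

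Markers of cells that a sort of live CD3+ CD4+ Foxp3+ cells should leave out were measured beside these groups. Of the myeloid list, Ctss, the protease cathepsin S, rose in VAT KO from 12.9 ± 1.07 to 35.4 ± 13.6 RPKM (log2 change 1.31 ± 0.25, adjusted p = 0.0449; SD, n = 3 each), while Fcer1g, an Fc receptor chain of myeloid cells, stood at 0.13 ± 0.44 (adjusted p = 0.9995), and the list of 3 tested genes was not called (1 rose adjusted over the list alone, median 0.13, camera adjusted p = 0.0941). The Ctss call was not robust: it was lost without VAT KO replicate 2 (1.10, adjusted p = 0.263), VAT KO replicate 3 (1.16, adjusted p = 0.236), any one VAT WT library or either spleen KO library (0.0874 and 0.0875). The 4 measured myeloid genes summed to 20.25, 45.6 and 45.41 RPKM in VAT KO against 13.98, 15.22 and 12.31 in VAT WT. Ctss, at the means above, made up most of these sums, so they largely repeat its rise. Of the 16 markers fixed for this list, only these 4 were among the 10992 genes that the filter left. Ctss was far higher in spleen, at 206 ± 42.1 RPKM in WT and 182 ± 3.55 in KO (n = 2 each). The 9 B cell genes were all lower in VAT KO, none past the threshold (0 adjusted over the list alone), with H2-Ab1 at -0.76 (adjusted p = 0.899) and Cd79a at -0.70 (0.950). The median was -0.61 (camera adjusted p = 0.00187; adjusted p = 0.426 with an estimated correlation). Without VAT WT replicate 2, whose B cell markers summed to 211.9 RPKM against 86.95 and 55.19 in the other VAT WT libraries, the B cell median was -0.05 (camera adjusted p = 0.706). The same sums in VAT KO were 66.23, 53.84 and 108.5 RPKM. The list of CD8, NK and gamma-delta T cells, with 3 measured members, had a median of -0.13 and summed to 6.163 to 18.95 RPKM in VAT and 16.78 to 28.62 in spleen. Of 9 neutrophil genes the filter left Mmp9 alone, at 112.3 to 217.1 RPKM in VAT against 0.387 to 4.925 in spleen. Of 12 adipocyte genes it left Lipe alone, at 1.633 to 3.397 RPKM over all libraries. The 2 genes left for stroma and endothelium summed to 8.928, 12.13 and 10.73 RPKM in VAT KO against 5.16, 4.796 and 7.626 in VAT WT. In spleen they summed to 16.99 to 35.06. Of 9 red cell genes 0 were left. The filter's rule is not given, so the genes it removed may have been low. Mmp9 alone thus does not show that neutrophils were present.

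In spleen the same comparison asked for the effect of the deletion in Tregs outside fat. Limma called 0 of 10429 genes there (smallest adjusted p = 0.244), with 873 at an unadjusted p under 0.05 against 521 by chance. The 4 genes with the smallest p, which did not pass, were Apobec3 (log2 change -2.01 ± 0.32, 4.76 ± 0.07 RPKM in KO against 23.7 ± 11.7 in WT; SD, n = 2 each; adjusted p = 0.244), Srebf2, Nfil3 (-1.03 ± 0.20, adjusted p = 0.306), a transcription factor, and the zinc finger gene Zfp189 (-1.70 ± 0.33, 0.306). The cholesterol synthesis list was lower in spleen KO too. Of its 20 enzymes 17 lay below 0, 0 passed, and 8 fell adjusted over the list alone. The median was -0.58 (camera adjusted p = 3.6e-07; adjusted p = 0.711 with an estimated correlation). Sqle stood at 0.375 against 4.87 RPKM (-1.95 ± 0.38, adjusted p = 0.306), Cyp51, lanosterol demethylase, at 2.58 against 13.0 (-1.95 ± 0.38, 0.306), and Fdft1, squalene synthase, at -1.12 (0.461). Of the sterol uptake list, which was not called (median -0.16, camera adjusted p = 0.205; 1 fell adjusted over the list alone), Insig1 stood at -1.01 (adjusted p = 0.581) and Insig2, a second protein that holds SREBPs back, at -0.46 (0.596). The 31 genes of oxidative phosphorylation had a median of -0.29 with 30 below 0 and 0 past the threshold, singly or adjusted over the list alone (camera adjusted p = 0.000107; adjusted p = 0.812 with an estimated correlation), with Sdhc at -0.44 (adjusted p = 0.594) and Ndufv2 at -0.48 (0.596). All 25 ribosomal protein genes lay below 0 (median -0.19) with 0 past the threshold, singly or adjusted over the list alone, among them Rpl3 at -0.49 (adjusted p = 0.594) and Rps6 at -0.29 (0.699). Camera gave an adjusted p of 0.0430 (adjusted p = 0.848 with an estimated correlation). The naive and lymphoid homing median was 0.22 (camera adjusted p = 0.104), the interferon median -0.28 (0.104), and no further list was called. Adjusted over the list alone, 4 of 18 immediate early and dissociation genes rose (median 0.03), 1 of 18 genes of fatty acid oxidation rose and 1 fell, and 3 of 21 genes of the adipose Treg programme rose and 2 fell (median -0.004).

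These spleen results rested on the 2 spleen WT libraries. Leaving out 1 of them leaves 1 spleen WT sample with no spread of its own, so only the changes of genes and lists are given, without p-values. The number of genes called moved widely between these fits. Apobec3 and Sqle stood at -2.51 and -2.63 without replicate 2, and at -1.51 and -1.27 without replicate 3. Without replicate 3, changes were -1.16 for Nfil3, -1.91 for Zfp189 and -1.47 for Cyp51. They were -0.87 for Ndufv2, -0.75 for Rpl3 and -0.72 for Rps6. The cholesterol call was lost without spleen WT replicate 3 (median -0.50). Without spleen WT replicate 2 the oxidative phosphorylation median turned to 0.12 and the ribosomal median to 0.23. The ribosomal call was lost without spleen KO replicate 2, which leaves 1 spleen KO sample (median -0.09). It was also lost without VAT KO replicate 2 (camera adjusted p = 0.0598), VAT WT replicate 1 (0.0554) or VAT WT replicate 2 (0.0511). Processing ended it with no filter (0.0738), quantile normalization (0.291), the 2 groups alone (0.0663) or replicate numbers as a block (0.0502).

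Whether the deletion acted differently in the 2 tissues was tested by the interaction of genotype and tissue. Limma called 0 genes (smallest adjusted p = 0.308), with 738 at an unadjusted p under 0.05 against 521 by chance, so no single gene was shown to respond differently. The 4 genes with the smallest p were Timp2, an inhibitor of metalloproteinases (1.54 ± 0.26), Serpina3g (2.19 ± 0.38), Zfp189 (2.40 ± 0.43) and Rilpl2 (1.24 ± 0.24), each at an adjusted p of 0.308. Ccr1 stood at -1.53 and Cxcl2 at -1.29 (adjusted p = 0.308 each), and Lrrc32 at 1.41, Tcf7 at 1.28 and Txk at 1.30 (0.543 each). Camera called 11 lists in this comparison, and 0 of them held with an estimated correlation (adjusted p from 0.398 to 0.752). The count of 0 was not steady when 1 spleen library was left out, which leaves 1 sample in its group. Across all 10429 genes the KO effects in VAT and in spleen had a Pearson r of 0.092 and a Spearman rho of 0.071, and 5483 genes (52.6%) had the same sign; genes are not independent replicates, so the correlation has no p. Among the 44 genes called in VAT, 31 had the same sign in spleen (r = 0.796 across these genes), and without Srebf2 30 of 43 did (r = 0.751). The r over all genes was 0.048 without spleen WT replicate 3 and 0.059 without VAT WT replicate 2. With 0 spleen calls, 0 called genes were shared.

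The comparison of VAT WT with spleen WT asked how adipose Tregs differ with Srebf2 intact. Tissue and its handling cannot be told apart here, so genes that respond to dissociation may reflect either. Fos, Atf3, Hspa1a and Hspa1b, named next, belong to the immediate early and dissociation list. Among the largest rises, Cxcl2, a neutrophil-attracting chemokine, stood at 221 ± 39.1 RPKM in VAT against 0.012 ± 0.017 in spleen (log2 change 7.76 ± 0.19; SD, n = 3 and 2), Areg, the repair factor amphiregulin, at 578 ± 82.2 against 4.87 ± 0.80 (6.62 ± 0.22), and Fos, an early response transcription factor, at 617 ± 71.1 against 2.10 ± 1.34 (7.70 ± 0.29). Other large rises were Ltb4r1 (7.68), a receptor for leukotriene B4, Atf3 (6.68), a stress response factor, and Cxcr6 (6.16), a chemokine receptor, with Hspa1b (7.54) and Hspa1a (6.63), heat shock genes so alike that reads may be split between them. Among the largest falls were Dtx1 (-4.69), a Notch pathway ligase, Igfbp4 (-4.23), Id3 (-4.19), an inhibitor of E proteins, Nsg2 (-4.17) and Lta (-4.02), lymphotoxin alpha, with Ces2c (-4.52) and Apol7e (-4.22), members of families with close copies and so uncertain. Each of these had a limma adjusted p of 6.1e-05 or less. Foxp3 was higher in VAT (0.89 ± 0.17, adjusted p = 0.00265), and Srebf2 stood at 0.33 ± 0.37 (0.543). Limma called 2723 genes, 1116 higher and 1607 lower in VAT, 1378 of them at least 2-fold. With scaling by median ratios the split was 1397 higher and 1038 lower, or 57.4% higher in place of 41.0%, and the median of all genes moved from -0.12 to 0.02. The count was 1718 without spleen WT replicate 2.

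By list, 20 of 21 genes of the adipose Treg programme rose in VAT WT (20 adjusted over the list alone, where 1 fell). The median was 3.13 (camera adjusted p = 7.7e-29; adjusted p = 0.00578 with an estimated correlation). They included Ccr1 (6.08), Areg and Plin2 (4.46), which coats lipid droplets. Batf, a transcription factor of tissue Tregs, was the member that did not rise, at -0.38 (adjusted p = 0.0952), and the one that fell adjusted over the list alone. It was named after its value was seen, and stood at -0.61 without spleen WT replicate 3, which leaves 1 spleen WT sample. Of the immediate early and dissociation list 16 of 18 rose (17 adjusted over the list alone), among them Atf3, Fos and Dusp1 (4.70). The median was 4.13 (camera adjusted p = 2.3e-27; adjusted p = 0.00645 with an estimated correlation). Of the naive and lymphoid homing list 13 of 14 fell, with Tcf7 at -2.92 and Actn1 at -2.75, and 1 rose, Il7r, the IL-7 receptor (1.32, adjusted p = 5.4e-05), named after its value was seen. The counts adjusted over the list alone were 13 and 1, and the median was -2.51 (camera adjusted p = 2.1e-08; adjusted p = 0.289 with an estimated correlation). Of the interferon response list 14 of 18 fell (16 adjusted over the list alone), with Usp18 at -2.84 and Gbp2, whose family has close copies, at -1.56. The median was -1.46 (camera adjusted p = 5.5e-08; adjusted p = 0.0789 with an estimated correlation). Of the genes induced by the T cell receptor 7 of 15 rose and 3 fell (8 and 3 adjusted over the list alone), led by Nr4a1 (4.95) and Nfkbid (4.13). Nr4a1 is also a member of the immediate early and dissociation list. The median was 0.46 (camera adjusted p = 0.000486; adjusted p = 0.307 with an estimated correlation).

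All 25 ribosomal protein genes fell (25 adjusted over the list alone), with Rpl3 at -0.94 and Rpl4 at -0.90. The median was -0.90 (camera adjusted p = 1.2e-08; adjusted p = 0.648 with an estimated correlation). Part of this fall rested on spleen WT replicate 2. Without it, which leaves 1 spleen WT sample, the ribosomal median of spleen KO against spleen WT turned from -0.19 to 0.23. The ribosomal level of spleen WT was thus lower without that library. Of oxidative phosphorylation 9 of 31 fell (14 adjusted over the list alone), with Ndufa4 at -1.54 and Sdha at -0.54 (adjusted p = 0.0118). The median was -0.46 (camera adjusted p = 0.000301; adjusted p = 0.648 with an estimated correlation). This list was not called without spleen WT replicate 2 (median -0.13, camera adjusted p = 0.582), nor did Sdha pass (-0.40). Of the myeloid list 2 of 3 fell (2 adjusted over the list alone), Ctss (-3.89) and Adgre1 (-1.02, adjusted p = 0.0137). The median was -1.02 (camera adjusted p = 0.0316; adjusted p = 0.307 with an estimated correlation). The other lists were not called, but some held strong changes both ways. In the core Treg list 6 of 19 rose and 6 fell (7 and 6 adjusted over the list alone), with Ctla4, an inhibitory receptor, at 1.76 and Izumo1r at -3.52. Its median was 0.15, its mean -0.35, and camera's direction was up (adjusted p = 0.603). Among apoptosis and survival genes 4 of 16 rose and 4 fell (the counts were the same adjusted over the list alone), with Cdkn1a (4.66), a cell cycle inhibitor, and Pmaip1 (2.99), the death factor Noxa, higher and Bcl2 (-2.06), a survival factor, and the death receptor Fas (-2.28) lower. The median was -0.09, the mean 0.27 and camera's direction up (adjusted p = 0.603). Of 18 genes of fatty acid oxidation 2 rose and 1 fell (2 and 1 adjusted over the list alone), among them Cpt1a, which loads fatty acids into mitochondria (1.91 ± 0.18, adjusted p = 9.2e-06), and Etfa (-0.70 ± 0.16, 0.00593; median 0.12, camera adjusted p = 0.200). Of cholesterol synthesis 3 of 20 rose (1 adjusted over the list alone), among them Hsd17b7 (1.66, adjusted p = 0.0103) and Nsdhl (0.81, adjusted p = 0.0269), with a median of 0.16 and no call (camera adjusted p = 0.148). Hsd17b7 did not pass without spleen WT replicate 2 (1.02), nor did Nsdhl without spleen WT replicate 2 (0.74), VAT WT replicate 1 (0.81) or VAT WT replicate 3 (0.74). Medians of the lists not called also were 1.41 for type 1 and cytotoxic genes (4 of 10 rose, or 6 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.102), 0.39 for fatty acid synthesis (3 rose, 1 fell), -0.11 for proliferation (2 fell, or 1 adjusted over the list alone), -0.01 for isoprenoid enzymes (5 fell), 0.36 for B cells and -0.47 for CD8, NK and gamma-delta T cells (1 fell).

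The comparison of VAT KO with spleen KO asked how adipose Tregs differ with Srebf2 deleted. Tissue and its handling cannot be told apart in this comparison either. Areg, Cxcl2 and Fos were again among the largest rises. Areg stood at 511 ± 27.3 RPKM in VAT against 3.70 ± 1.86 in spleen (log2 change 6.83 ± 0.22; SD, n = 3 and 2), Cxcl2 at 141 ± 15.8 against 0.607 ± 0.274 (6.47 ± 0.19) and Fos at 414 ± 13.6 against 3.57 ± 2.32. Il10, the suppressive cytokine, stood at 188 ± 35.6 against 3.64 ± 3.37 (5.55 ± 0.35). Ltb4r1 (6.73), Atf3 (6.50), AA467197 (5.74) and Ier3 (5.22) made up the other large rises. Igfbp4 (-3.96), Dtx1 (-3.70), Id3 (-3.47), Sostdc1 (-2.97) and Lta (-2.94) were among the largest falls, with Gbp2b (-3.06), Ly6k (-2.94) and Ces2c (-2.92), whose families have close copies. Each had a limma adjusted p of 0.000767 or less except Ly6k (0.00503), which did not pass without spleen KO replicate 3 (-2.46). Foxp3 was higher in VAT (0.79 ± 0.17, adjusted p = 0.00839), a call lost without spleen KO replicate 3 (0.71), and Srebf2 stood at -0.89 ± 0.37 (0.135). Limma called 1522 genes, 798 higher and 724 lower in VAT, 891 of them at least 2-fold. With scaling by median ratios the split was 969 higher and 492 lower, or 66.3% higher in place of 52.4%, and the median of all genes moved from -0.09 to 0.02. The count was 747 without spleen KO replicate 3, 784 without spleen KO replicate 2 and 1012 without VAT KO replicate 1.

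By list, 20 of 21 genes of the adipose Treg programme rose in VAT KO over spleen KO (20 adjusted over the list alone), with Plin2 at 3.68. The median was 2.99 (camera adjusted p = 4.9e-37; adjusted p = 0.00285 with an estimated correlation). Of the immediate early and dissociation list 16 of 18 rose (17 adjusted over the list alone), with Dusp1 at 4.24 and Junb at 3.81. The median was 3.96 (camera adjusted p = 2.1e-31; adjusted p = 0.00440 with an estimated correlation). Of the naive and lymphoid homing list 13 of 14 fell, with Igfbp4 and Actn1 (-2.20), and Il7r rose (1.29, adjusted p = 0.000108). The counts were the same adjusted over the list alone and the median was -1.53 (camera adjusted p = 2.4e-08; adjusted p = 0.195 with an estimated correlation). Of the genes induced by the T cell receptor 8 of 15 rose and 0 fell (9 and 2 adjusted over the list alone), with Nr4a1 at 4.43 and Nfkbid at 3.23. The median was 0.87 (camera adjusted p = 7.1e-07; adjusted p = 0.157 with an estimated correlation). Of the interferon list 10 of 18 fell (13 adjusted over the list alone), with Usp18 at -2.69 and Gbp2 at -1.38. The median was -0.94 (camera adjusted p = 1.4e-07; adjusted p = 0.0868 with an estimated correlation). Of type 1 and cytotoxic genes 4 of 10 rose (5 adjusted over the list alone), with the chemokine Ccl5 at 2.59 and the granule protein Nkg7 at 2.53. The median was 1.91 (camera adjusted p = 2.3e-05; adjusted p = 0.195 with an estimated correlation). Of ribosomal protein genes 6 of 25 fell (21 adjusted over the list alone). The median was -0.56 (camera adjusted p = 7.1e-07; adjusted p = 0.588 with an estimated correlation). Rps18 was among them (-0.72, adjusted p = 0.0229) but did not pass without spleen KO replicate 2 (0.0991), spleen KO replicate 3 (0.159), VAT KO replicate 1 (0.0874) or VAT KO replicate 2 (0.0752). Tissue effects in WT and in KO, which share no library, had a Pearson r of 0.854 and a Spearman rho of 0.708 across the 10429 genes. They shared 661 genes called higher in VAT, where independent lists would share 85.4, and 569 called lower, where independent lists would share 111.6.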

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

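The tests of mixed-in spleen-like RNA and of other cell types in spleen WT replicate 2 were chosen only after the results they bear on were seen. For 11 gene lists, camera's test of the interaction called a difference between the KO effect in VAT and that in spleen, and none of the 11 was called with an estimated correlation (adjusted p from 0.398 to 0.752). The median difference, VAT minus spleen, was -0.20 for cholesterol synthesis (camera adjusted p = 0.0460), -0.30 for the adipose Treg programme (0.0089), 0.32 for core Treg genes (0.0107), 0.53 for naive and lymphoid homing (0.00190), -0.31 for immediate early and dissociation genes (0.000148), 0.34 for interferon response (0.0089), 0.45 for type 1 and cytotoxic genes (0.0077), 0.24 for oxidative phosphorylation (0.00772), 0.32 for ribosomal proteins (0.00250), -0.63 for B cell markers (0.0089) and 0.84 for myeloid markers (0.0107). Without spleen WT replicate 2, which leaves 1 spleen WT sample, the difference turned for oxidative phosphorylation (-0.15) and ribosomal proteins (-0.12). It was then not called for cholesterol synthesis, interferon, type 1 genes or B cells. Without spleen WT replicate 3 it was not called for core Treg genes (0.130), naive and lymphoid homing (0.1003) or the adipose programme (0.0893). Without spleen KO replicate 3 the calls lost were the adipose programme (0.236), cholesterol synthesis (0.0750), B cells (0.170) and myeloid markers (0.0630), and without spleen KO replicate 2 they were cholesterol synthesis (0.0910), type 1 genes (0.0813) and ribosomal proteins (0.0910). Cholesterol synthesis was also not called without VAT KO replicate 2 (0.0830), VAT KO replicate 3 (0.0945) or VAT WT replicate 3 (0.188), nor B cells without VAT WT replicate 2 (0.405). Processing ended calls too: cholesterol synthesis with a pseudocount of 0.1 (0.103) or a mean of at least 5 RPKM (0.628), the adipose programme with quantile normalization (0.0517), B cells with a mean of at least 5 RPKM (0.110) and myeloid markers with a pseudocount of 0.1 (0.0542). Immediate early and dissociation genes were called without each single library.

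The VAT KO libraries lay closer to spleen than the VAT WT libraries, at 29.4 to 36.3 against 41.3 to 46.5 on an axis from spleen (-45.4 to -35.2) to VAT. A weaker dissociation response as the whole cause was tested with each library's immediate early mean as a covariate. The naive and lymphoid homing list kept a median of 0.742 against 0.691 without it (camera adjusted p = 2.9e-13). Without the covariate the list was already not called with an estimated correlation (camera adjusted p = 0.106). The SE of the list mean was 0.253 against 0.206, and the calls of single genes fell from 44 to 1. The covariate's slope came only from differences within groups, so this test cannot decide. Such differences were small in VAT (SD 0.076 in WT and 0.08 in KO) and largest between the 2 spleen KO libraries (4.254 and 4.716). With the covariate camera no longer called sterol uptake (median -0.007 against -0.107, adjusted p = 0.107) or B cells (-0.337 against -0.61, 0.0744), and the type 1 median was 0.308 against 0.561. Why those calls ended was not tested. The immediate early list itself was not called either (-0.129 against -0.221, camera adjusted p = 0.107). That loss was fixed in advance, since the covariate is the mean of the list's own genes. Lymphoid Tregs, which a sort on CD3, CD4 and Foxp3 would keep, or their RNA mixed into the VAT KO libraries stay open. Of the 15 genes at least 8-fold higher in spleen 100% were higher in VAT KO, which restates the pattern and does not favour a mixture. They gained a median share of 8.7% of the spleen level (bootstrap interval over genes 5.5% to 10.5%). That share alone would move the 85 genes at least 8-fold higher in VAT by -0.13. The observed median was -0.37 (bootstrap interval over genes -0.41 to -0.31). At 4-fold the share was 13.7% (14.7% at 20 RPKM or more), which would give -0.21 (-0.23) against -0.32. The bootstrap drew genes, which are not independent, so its intervals leave out the spread between libraries. The profile of such cells is unknown, so a mixture and a shift within each cell cannot be told apart here. An effect of the deletion on the state of adipose Tregs, the difference that the design names, remains open and untested.

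Spleen WT replicate 2 lay apart from the other 3 spleen libraries. Other cell types, which the sort should remove, stay open. The highest ratio of a summed list of other-cell markers to its mean in those libraries was 1.35, for CD8, NK and gamma-delta T cells, but the level of such markers in every spleen library would hide a small share. All 4 myeloid markers (240.5 RPKM in sum against 182.7) and 2 of the 3 of CD8, NK and gamma-delta T cells were higher than in each of those libraries. Coverage that depends on transcript length may account for part of the gap, since the library's deviation across genes followed length with a Spearman rho of -0.36, against -0.151 to 0.266 in the other libraries. No biological explanation was tested for it.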

How the results depend on the processing

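The direction of Srebf2 in both tissues and of the cholesterol synthesis list in both tissues, and of the adipose Treg programme in VAT, was the same under every alternative run. Sizes and counts were less steady. Over all alternatives the VAT KO median ran from 0.319 to 1.044 for naive and lymphoid homing, -0.491 to -0.165 for fatty acid synthesis and -0.826 to -0.423 for cholesterol synthesis. It ran from -0.161 to -0.043 for sterol uptake, -0.338 to -0.079 for immediate early and dissociation genes and 0.11 to 0.218 for core Treg genes. A pseudocount of 0.1 gave 2 calls in spleen and 2 for the interaction, a pseudocount of 5 gave 20 in VAT KO against WT, and the 2 groups alone gave 1757 in VAT WT against spleen WT. Sample weights gave 83 in VAT KO against WT, 1318 in VAT WT against spleen WT and 2329 in VAT KO against spleen KO, with spleen WT weighted at 0.38. Requiring a 2-fold change left 1378 and 891 tissue calls. The correlation of KO effects was 0.13 at a mean of at least 5 RPKM. With an estimated correlation the lists called were 0 in VAT, 0 in spleen, 2 and 2 between tissues and 0 for the interaction, against 9, 3, 8, 7 and 11. Fry called 4, 0, 8, 8 and 1 in the same order. In VAT these were core Treg genes (fry adjusted p = 0.00421), cholesterol synthesis (0.00851), naive and lymphoid homing (0.0446) and the adipose Treg programme (0.0484). Fry did not call the other lists that camera called in VAT (fry adjusted p from 0.110 for sterol uptake to 0.530 for B cells). Fcer1g in VAT turned to -0.22 with a pseudocount of 0.1, without passing. Single named genes were followed under all alternatives except the 2-fold threshold. In VAT KO against WT 711 of their values kept their direction and side of the threshold. There 100 no longer passed, 18 came to pass and 6 changed sign. In spleen these were 361, 0, 13 and 2, and in VAT WT against spleen WT 904, 12, 2 and 1. In VAT KO against spleen KO they were 633, 14, 1 and 0, and for the interaction 229, 0, 9 and 1. The 2-fold threshold, which bears on counts only, and the 2 groups alone change the threshold and the samples by construction. Apart from these 2 settings, the cause of such moves was not tested.

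The interaction has no fit with 2 groups alone. Each library was left out in turn, with the filter applied again, and a lone sample was assumed to vary like the other groups. Genes called then ranged from 2 to 59 in VAT KO against WT, 0 to 1395 in spleen, 1718 to 3892 and 747 to 2209 between tissues in WT and in KO, and 0 to 514 for the interaction. Lists called ranged from 9 to 12, 2 to 6, 8 to 9, 7 to 9 and 5 to 12 in the same order. Srebf2 ranged from -2.99 to -1.92 in spleen, the cholesterol median there from -0.73 to -0.48, and the correlation of KO effects from 0.048 to 0.126. Foxp3 changed sign without passing, over -0.066 to 0.077 in VAT, -0.055 to 0.227 in spleen and -0.238 to 0.044 for the interaction, as did Fcer1g in VAT (-0.55 to 0.50) and Srebf2 between tissues in WT (-0.21 to 0.87). Rps6 in spleen ran from -0.72 to 0.13, both with 1 spleen WT sample left.

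Replicate numbers are shared between groups. Deviations of samples with the same number had correlations from -0.147 to 0.184, with 1 of 13 over 0.1, and 4 of 10 samples matched best with their own number. Most of these pairs cross genotypes and cannot come from 1 mouse. Within a genotype, VAT and spleen correlated at 0.092 and 0.184 in WT and at 0.003 and 0.046 in KO. A shared mouse was thus neither shown nor excluded. With the replicate block the calls were 39, 0, 2066, 1096 and 0 in the order above, and with samples of 1 genotype and number as a random block (within-block correlation 0.129) they were 44, 0, 3095, 1748 and 0. Depth is unknown, so what it limits was not tested.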

Other observations

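The averaged effect of the deletion, the Ms4a genes and the genes near Srebf2 were chosen for testing only after the data were seen. Averaged over both tissues, limma called 8 genes between KO and WT, 7 lower and 1 higher, and 7 of them were also called in VAT alone. Srebf2 (-3.06), Sqle (-2.36) and Hmgcs1 (-1.23) were among those that fell, with Cyp51 (-1.66, adjusted p = 0.0260), which had not passed in VAT alone (-1.38, 0.118). Apobec3 (-1.95) and Cbx7 (-1.79) fell too, and 1110032F04Rik, a gene of unknown function, rose (1.39). Other settings gave 5 to 9 calls. Without single VAT libraries there were 5 (VAT KO replicate 2 or VAT WT replicate 2) and 4 (VAT KO replicate 3). With 1 spleen library left out, which leaves 1 sample in its group, some counts were far higher.

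In VAT KO 3 genes of the Ms4a family, membrane proteins encoded side by side on chromosome 19, rose. Ms4a6b stood at 50.8 ± 5.08 RPKM in KO against 24.3 ± 2.54 in WT (log2 change 1.04 ± 0.13, limma adjusted p = 0.00871; SD, n = 3 each), Ms4a4b at 60.4 ± 9.22 against 26.7 ± 3.70 (1.15 ± 0.16, 0.0110) and Ms4a6c at 6.49 ± 1.07 against 2.16 ± 0.78 (1.27 ± 0.21, 0.0259). None of the 3 passed without VAT KO replicate 2 (0.96, 1.1 and 1.28), VAT KO replicate 3 (1.04, 1.06 and 1.16) or VAT WT replicate 1 (1.00, 1.13 and 1.38), nor did Ms4a6c without VAT WT replicate 2 (1.04) or either spleen KO library (1.27). In spleen the changes were 0.08, -0.20 and 0.19, without passing, and no gene passed the test of the interaction. Genes of this family have close copies, so reads may be split between them. Of the 10 splits of the 6 VAT libraries into 3 and 3, 1 gave as many calls as the real split, the real split itself, with 44 calls against at most 0 in the other splits, and 10 splits are too few for a share under 0.05.

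Apobec3 and Cbx7, near Srebf2, were called in VAT, and no gene was called in spleen with all libraries. Leaving out a spleen WT library leaves 1 sample in that group, so only changes in spleen are given. Cbx7 stood at -2.62 without replicate 2 and -1.26 without replicate 3, and Apobec3 at -2.51 and -1.51. Ift27 stood at -1.26 without replicate 3. In VAT the call of Cbx7 was lost without any one VAT library or either spleen KO library (adjusted p from 0.0794 to 0.242), and that of Apobec3 without VAT KO replicate 2 (0.0669), VAT KO replicate 3 (0.0694) or VAT WT replicate 1 (0.0562). Within 10 Mb of Srebf2 on chromosome 15, 4 of 197 tested genes (2.03%) passed an unadjusted p of 0.05 with the same sign in VAT and in spleen, against 47 of 10228 elsewhere (0.46%). They were Apobec3 (79892058 to 79918218; -1.89 in VAT and -2.01 in spleen), Cbx7 (79915804 to 79971143; -1.64 and -1.94), Ift27 (-0.50 and -0.94) and Ly6k (1.66 and 2.01), of which Apobec3 and Cbx7 overlap and prompted the test. Without these 2, 2 of 195 remain (odds ratio 2.24, 95% interval 0.26 to 8.68, Fisher's exact p = 0.233), and 101 of 464 windows on other chromosomes held as large a share (highest 7.69%). DNA of another strain kept around the floxed allele is a candidate explanation that these counts do not decide, so it and an effect of the deletion itself cannot be told apart. Which strains the mice carried was not tested.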
